A study of Homo sapiens with 4 samples.

How the data were processed

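Poly(A) RNA was sequenced from MCF10A cells, an immortalised but non-tumorigenic human mammary epithelial line, carrying 1 of 4 pBabe retroviral constructs: the empty vector, GFP, the microRNA miR-105 or MYC. There was 1 library per construct, so no group had a replicate. Per the labels' protocols, the cells grew in DMEM/F12 with horse serum, insulin, EGF, cholera toxin and hydrocortisone, total RNA was taken with TRIzol, and libraries followed an Illumina poly(A) protocol.

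The submitters' processing notes name TopHat2, edgeR and the human genome build hg19, without versions. The read counter, the gene annotation and the strand setting are not given in the sources used here. The single table used held 1 normalised value per gene symbol and library. The deposited values were a depth-adjusted signal and not the raw counts that the design had assumed, because they were not whole numbers and their totals lay between 9220845 and 10307368. They had the form of edgeR pseudo-counts, which map the quantiles of each library onto a common library size. Inverting that mapping at a common dispersion of 0.0553, with the vector and GFP libraries adjusted as 1 group and the other libraries each on their own, gave whole reads for 100% of the 18859 values of every library. The largest relative residual was 2.67e-06, against a tolerance of 1e-05. Recovered reads were used for everything below, and the values as deposited, without further scaling, were used as an alternative chosen after the data had been seen. Of the 18859 lines, 19 repeated another line exactly and were dropped, leaving 18840 genes. A symbol with differing lines, TBC1D31, was used as given. On simulated counts the inversion returned the exact reads for 99.9% of values in the vector and GFP libraries and 100% in the others.

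The recovered totals were 9138429 reads for the vector library, 14025115 for GFP, 6859698 for miR-105 and 9795159 for MYC. Depth-normalised expression (CPM) was computed from these totals and TMM factors of 1.0122, 0.987, 0.929 and 1.0768 in the same order, so that 1 read was worth 0.108, 0.0722, 0.157 and 0.0948 CPM. Error bounds are exact conditional binomial (Clopper-Pearson) 95% intervals of a ratio, or exact Poisson 95% intervals of a level. They cover counting error alone: reads without molecular identifiers are not independent molecules, and the spread between cultures cannot be estimated from 1 library. A fold against a library with 0 reads was computed against a floor of 3 reads in that library and is written as at least that fold. It leaves out the counting error of the other library, so the exact 95% lower limit is smaller.

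No test was the main result. Genes with a mean of at least 1 CPM over the 4 libraries were compared, 12484 of 18840. Log2 fold changes were taken after adding 0.5 CPM, which understates the change of low genes, while folds given for single genes are ratios of CPM with nothing added. A gene was counted as different in the library labelled miR-105 or MYC if it was at least 2-fold higher, or at least 2-fold lower, than in the vector library and in the GFP library. The GFP and vector libraries were compared with each other by the same threshold. To show what counting error and culture-to-culture scatter of the size seen between the controls would give, 100 sets of unchanged libraries were drawn at the dispersion between the vector and GFP libraries, 0.0492. A count test was added by treating the vector and GFP libraries as replicates of 1 control group (edgeR quasi-likelihood and DESeq2, Benjamini-Hochberg adjusted p under 0.05). It leaves 1 residual degree of freedom, shared by all groups, and compares these libraries, not conditions.

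A total of 40 gene lists was fixed before the data were examined, together with the groups, the thresholds, the naming rule and all alternatives but the one named above. For growth they covered MYC targets, the MYC network of MAX partners, ribosome biogenesis with RNA polymerase I, cytosolic ribosomal proteins, and translation factors with tRNA synthetases. For metabolism they covered glycolysis, glutamine and amino acids, serine with one-carbon and nucleotide synthesis, nuclear-encoded oxidative phosphorylation, cholesterol, fatty acids, and lysosome with autophagy. For the cell cycle and stress they covered G1/S, G2/M, CDK inhibitors with p53 targets, the unfolded protein and ATF4 response, heat shock chaperones and hypoxia. For signalling and immunity they covered interferon-stimulated genes, MHC class I presentation, inflammatory and NF-kB targets, TGF-beta and YAP targets, EGFR and MAPK feedback, and the steroid and insulin response. For cell identity they covered epithelial junctions, mesenchymal regulators, extracellular matrix, squamous, basal and luminal genes. MicroRNA processing and vesicle release had 1 list each, fibroblast, immune, endothelial and erythroid markers stood for other cells, mitochondrial mRNAs, replication-dependent histones and immediate stress genes for RNA quality, and housekeeping genes for scaling. Of 1052 listed genes, 991 had a line in the table, and the 61 others are not analysed here. A member was counted as higher or lower if it differed at least 1.5-fold in the same direction from both controls. The median of a list was taken over its members' mean log2 fold change against both controls, and given as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with fewer than 5 measured members have no median.

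Named genes followed a fixed rule: MYC and its network partners MYCN, MYCL, MAX, MXI1, MXD1, MXD3, MXD4, MNT and MGA, the miR-105 loci with their host gene GABRA3, and TJP1; the 12 highest and 12 lowest counted genes of each labelled library by their smaller fold against the controls, at a mean of at least 5 CPM; the 5 highest and 5 lowest of GFP against vector; in each list the 2 highest and 2 lowest members per library; and up to 5 genes counted in both labelled libraries per combination of directions. Genes with near-identical copies (ALPP and ALPPL2, HSPA1A and HSPA1B, SNRPN and SNURF, metallothioneins, histones, the PSG and ADH1 families, ribosomal proteins with pseudogenes) may share reads and their values are uncertain. Some genes that the rule selects are not reported here.

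Sites for miR-105-5p (UCAAAUGCUCAGACUCCUGUGGU) were sought in 3′ UTRs of GRCh38 with the GENCODE 29 annotation, as matches to seed positions 2 to 8 or the same 7 bases with an A after them. GRCh38 was used for names, positions, transcript lengths, GC content and UTR sequence alone, and no coordinate was converted from the submitters' build. Genes with a site were compared with genes without one, and the difference was ranked among other words of the same length that occur in a similar number of genes, within 20%. Shifts between genes with and without a site carry bootstrap 95% intervals from 300 draws.

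Each step was tested on simulated counts. With 50 genes changed at each size, the 2-fold rule found 8%, 56%, 98% and 100% of genes changed by 1.5, 2.5, 4 and 8-fold in the miR-105 comparison, and 10%, 54%, 94% and 100% in the MYC comparison. It also called 87 unchanged genes among 12293 tested and 78 among 12297. Alternatives were DESeq2 size factors, library totals alone, reads thinned to the shallowest library, no expression filter, a mean of at least 5 CPM, a pseudocount of 0.1 or 2, either control alone, thresholds of 1.5 and 4-fold, other control pairings for correlations, members of other lists left out, and 8-base sites alone. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.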

Results

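The 4 libraries came from MCF10A mammary epithelial cells carrying the empty pBabe vector, GFP, miR-105 or MYC, with 1 library each. Read totals were 9138429 for the vector library, 14025115 for GFP, 6859698 for miR-105 and 9795159 for MYC. At least 1 read was seen for 16531, 15022, 13514 and 14854 genes in that order, and 12296, 12254, 11612 and 12291 genes reached 1 CPM. The 10 most abundant genes took between 4.55% (miR-105) and 6.15% (vector) of the reads. MiR-105 is a microRNA reported to act on MXI1, an antagonist of MYC, and on TJP1, the tight junction protein ZO-1, so the design sets the transcriptome of miR-105 cells beside that of MYC cells. Where a pair of folds is given for a gene, the first is against the vector library and the second against the GFP library.

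The construct genes were read first, as a check of the labels. MYC mRNA stood at 207 CPM in the vector library, 198 in GFP, 463 in miR-105 and 232 in the library labelled MYC. It was thus 1.12-fold (95% counting interval 1.05 to 1.19) and 1.17-fold (1.11 to 1.24) higher in the library labelled MYC, and 2.24-fold (2.11 to 2.37) and 2.34-fold (2.22 to 2.46) higher in the library labelled miR-105. The transcript that the MYC label names was therefore highest in another library, and each direction below belongs to the library labelled MYC or miR-105 and not to a measured excess of either construct. The read counter, the annotation and the extent of MYC sequence in the construct are not given in the sources used here, so a transcript of the construct that was counted in part, or not at all, would not be seen in these values. MXI1 (GRCh38 10:110207605-110287365), whose protein competes with MYC for MAX, was 5.82-fold (4.66 to 7.33) and 6.37-fold (5.13 to 7.98) lower in the library labelled miR-105. In the library labelled MYC it was 1.03-fold and 1.12-fold lower, a mean log2 fold of MXI1 in the MYC library of −0.10 that becomes 0.0059 when library totals alone set the scale. TJP1 (15:29699367-29968865) was 1.21-fold (1.13 to 1.29) and 1.77-fold (1.67 to 1.88) lower with the miR-105 label, and 2.66-fold (2.48 to 2.87) and 3.91-fold (3.66 to 4.18) lower with the MYC label, while the controls themselves differed 1.47-fold. The loci MIR105-1 (X:152392219-152392299) and MIR105-2 (X:152394412-152394492) lie inside GABRA3, overlap none of its exons, and are not analysed here, since the table gave them no line. GABRA3 had 1 read, in the library labelled miR-105. MYCN had 0 reads in all 4 libraries, which allows up to 0.217 to 0.471 CPM depending on depth, and MYCL lay between 0.627 and 1.61 CPM.

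**Figure D1:**
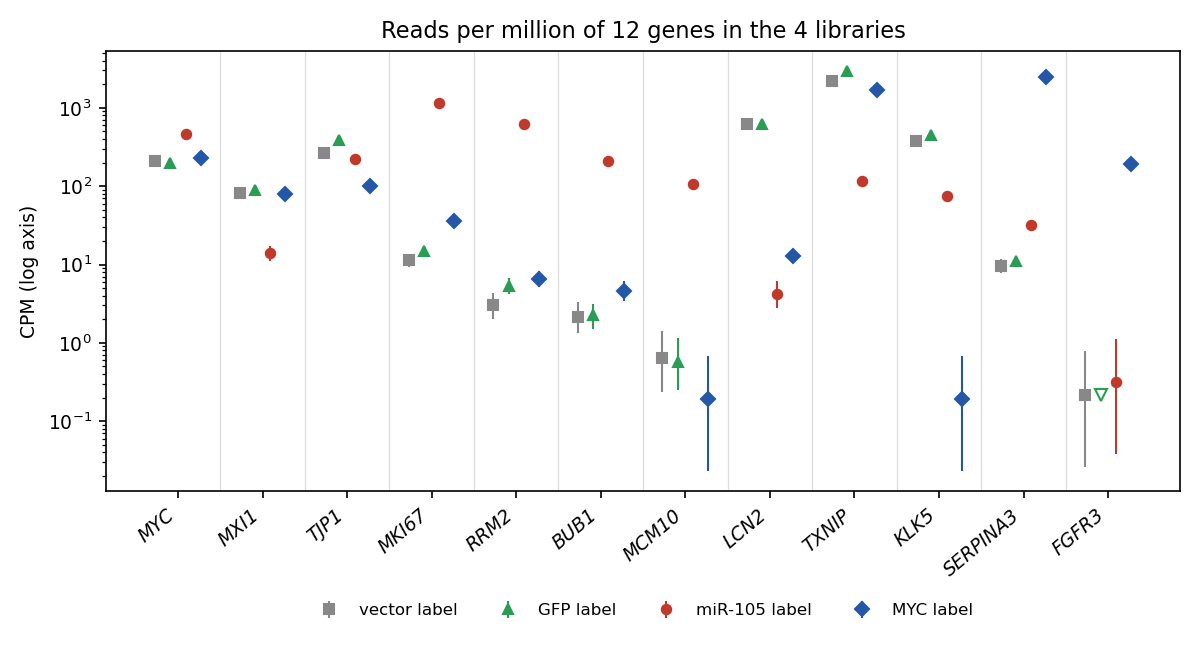
Expression of 12 genes in the 4 libraries, as CPM on a log axis, with squares for vector, triangles for GFP, circles for miR-105 and diamonds for the library labelled MYC, bars for exact Poisson 95% intervals, and hollow downward triangles for a library with 0 reads drawn at the 3-read floor. MYC is highest in the library labelled miR-105 (463 CPM), MKI67 stands at 1169 CPM there against 11.4 to 36.3 in the others, and KLK5 is at 0.190 CPM in the library labelled MYC against 372.5 and 447 in the controls.

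The library labelled MYC differed from both controls in genes of inflammation, antigen presentation and epithelial identity. Inflammatory and NF-kB target genes were higher, with 15 of 21 members at least 1.5-fold above both controls, 2 below and a median log2 fold of 2.62, and MHC class I presentation genes were higher with 10 of 16 members, 0 lower and a median of 1.11. TGF-beta and YAP targets, epithelial junction genes and squamous differentiation genes were lower in 12 of 19, 13 of 28 and 12 of 23 members, with medians of −1.398, −0.63 and −0.86. The acute-phase protease inhibitor SERPINA3 stood at 2458 CPM against 9.62 and 11.1 CPM in the controls, 255-fold (207.5 to 318) and 221-fold (189 to 261) higher. MYC mRNA differed from the controls by at most 1.17-fold in this library.

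Several of the highest genes had almost no reads in the controls. ADH1B, an alcohol dehydrogenase with close copies, stood at 168 CPM, 1552-fold (278 to 61343) above the single read of the vector library and at least 774-fold above GFP. The receptor kinase FGFR3 reached 191 CPM, 885-fold (245 to 7315) above 2 vector reads and at least 883-fold above GFP. Fibrillin FBN2 was 437-fold (121 to 3611) and at least 436-fold higher, and podoplanin PDPN 609-fold (109 to 24073) and at least 304-fold higher. The chitinase-like glycoprotein CHI3L1 was at least 195-fold and at least 291-fold higher, lactoferrin (LTF) at least 175-fold and 261-fold, and the potassium-chloride cotransporter SLC12A7 at least 163-fold and 243-fold. The protocadherin FAT2 was 453-fold (177 to 1664) and 181-fold (109 to 324) higher, and the collagen chaperone FKBP10 124-fold (67.3 to 259.5) and 309.7-fold (142 to 845). BST2 and SNURF completed the highest 12, at least 147-fold and at least 128-fold above vector, SNURF sharing reads with SNRPN.

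Genes of cornified and barrier epithelium filled the opposite end. KLK5, a serine protease of the epidermis, went from 372.5 and 447 CPM in the controls to 2 reads, 1965-fold (543 to 16230) and 2357-fold (652 to 19467) lower. The protease inhibitor A2ML1, also at 2 reads, was 864-fold (239 to 7139) and 1339-fold (370.3 to 11059) lower, and sciellin (SCEL), a cornified envelope protein, 259-fold and 351-fold lower. The epithelial transcription factor GRHL2 had 0 reads against 113 and 155 CPM, at least 398-fold and at least 547-fold lower. CD22 and the NADPH oxidase subunit CYBA likewise had 0 reads, at least 411-fold and 285-fold below vector. Also among the lowest 12 were TTC9, 214-fold and 281-fold lower; WNT7B, 259-fold (88.3 to 1260.1) and 306-fold (104.5 to 1486); ATP13A4, 488-fold (135 to 4036) and 448-fold (124 to 3701); MYPN, at 2 reads; and PSG4, at least 204-fold and at least 151-fold lower.

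Among growth lists, MYC targets and ribosome biogenesis genes held most of the higher members in the library labelled MYC. Of 55 MYC target genes, 24 were higher and 2 lower, with a median log2 fold of 0.62 at percentile 100 of the matched random lists; hexokinase HK2 was 9.54-fold and 8.42-fold higher and MCM4 1.92-fold and 2.49-fold lower. Ribosome biogenesis genes had 17 of 51 higher and 1 lower (median 0.53, percentile 100), among them WDR3 (2.95-fold and 2.44-fold), while RRP7A was 1.98-fold and 2.10-fold lower. Cytosolic ribosomal protein genes had 3 of 72 higher and 1 lower, RPS26, at 12.6-fold and 8.20-fold. The median of cytosolic ribosomal proteins in the MYC library was 0.46, but 0.0047 against vector alone and 0.91 against GFP alone. Translation factors and tRNA synthetases had 3 of 32 higher and 0 lower (median 0.24, percentile 98.8), including EPRS at 3.06-fold and 2.60-fold. The MAX partners had 2 of 10 higher, 0 lower and a median of 0.21 (percentile 78.6), MGA standing 2.90-fold and 1.60-fold above the controls, whereas MAX, MXD4 and MNT differed by less than 1.3-fold.

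Metabolic lists were higher in several branches. Glycolysis genes had 7 of 23 higher and 5 lower (median 0.33, percentile 97.9): the regulator PFKFB2 was 4.51-fold and 3.05-fold higher, pyruvate kinase PKM 2.28-fold and 2.09-fold lower. Glutamine and amino acid genes had 8 of 20 higher and 1 lower (median 0.47, percentile 99.7), with ornithine decarboxylase ODC1 at 4.56-fold and 4.97-fold. Serine, one-carbon and nucleotide synthesis genes had 14 of 28 higher and 0 lower (median 0.72, percentile 100), among them the serine pathway enzyme PSAT1 at 5.92-fold and 4.55-fold. Nuclear-encoded oxidative phosphorylation genes had 11 of 36 higher and 0 lower (median 0.68, percentile 100). Fatty acid synthesis genes had 9 of 15 higher and 2 lower (median 0.91, percentile 100), fatty acid synthase FASN reaching 5.05-fold and 4.34-fold and the desaturase SCD 5.17-fold and 3.97-fold. Cholesterol genes had 6 of 22 higher and 0 lower (median 0.30, percentile 97.3). Lysosome and autophagy genes had 7 of 20 lower and 2 higher (median −0.48, percentile 0.75), GABARAPL1 being 2.96-fold and 3.17-fold lower.

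Cell cycle genes divided. G2/M genes had 18 of 34 higher and 0 lower (median 0.75, percentile 100), CENPF by 7.18-fold and 6.51-fold and CDC25B by 6.17-fold and 10.6-fold. G1/S genes had 6 of 39 higher and 4 lower (median 0.10, percentile 56.1), cyclin D1 (CCND1) being 3.61-fold and 4.51-fold lower. CDK inhibitors and p53 targets had 7 of 23 lower and 2 higher (median −0.27, percentile 4.20): CDKN1A, which encodes p21, was 4.39-fold and 4.51-fold lower, but CDKN1C was 4.57-fold and 11.6-fold higher. Hypoxia genes had 10 of 19 lower and 3 higher (median −0.73, percentile 0.07), VEGFA being 2.42-fold and 3.91-fold lower and EGLN1 3.14-fold and 2.53-fold higher. The unfolded protein and ATF4 list had 2 of 25 higher and 3 lower, with a median of 0.11 and a mean of −0.12. Heat shock chaperones had 1 of 19 higher and 6 lower; the median of heat shock chaperones in the MYC library was −0.03 and the mean −0.34, and the median becomes 0.08 with library totals alone and 0.03 with the deposited values unscaled. HSPA1A and HSPA1B, which share reads, were 4.25-fold and 4.43-fold below vector. Immediate stress genes had 4 of 14 higher and 3 lower (median −0.13, percentile 27.9).

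Among immune genes, the mitochondrial superoxide dismutase SOD2, an NF-kB target, stood at 9921 CPM against 349 and 345, 28.4-fold (27.4 to 29.4) and 28.7-fold (27.9 to 29.6) higher. The chemokine CXCL2 was 46.4-fold and 78.1-fold higher, whereas lipocalin LCN2 was 47.3-fold and 48.4-fold lower. The MHC class I transactivator NLRC5 was 30.4-fold (17.9 to 56.0) and 39.8-fold (24.2 to 70.2) higher and the immunoproteasome subunit PSMB9 38.6-fold (14.8 to 143) and 20.999-fold (11.5 to 42.8), while HLA-C differed by 1.08-fold and 1.09-fold. Interferon-stimulated genes went both ways, 10 of 33 higher and 8 lower: IFI44L was 18.4-fold and 43.0-fold higher and EPSTI1 179.8-fold (61.1 to 875) and 161-fold (54.8 to 783) lower at 3 reads. The median of interferon-stimulated genes in the MYC library was −0.06 with a mean of 0.30, and becomes 0.04 with library totals alone and 0.26 without the expression filter.

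Epithelial and matrix lists had more members lower than higher in this library. Junction genes had 13 of 28 lower and 5 higher (percentile 0.11), claudin CLDN4 by 100.3-fold (69.7 to 150.1) and 109-fold (75.5 to 162), whereas the desmosomal cadherin DSC3 was 4.27-fold and 2.72-fold higher. Squamous genes had 12 of 23 lower and 2 higher (percentile 0.08), involucrin (IVL) by at least 60.4-fold and 87.9-fold; the median of squamous differentiation in the MYC library, −0.86, becomes −0.40 without the expression filter and −2.38 among members of at least 5 CPM. Luminal genes had 6 of 11 lower and 2 higher (median −1.21, percentile 0.10), among them ALDH1A3 at 50.8-fold and 76.4-fold. Basal genes had 9 of 17 lower and 2 higher (median −0.74, percentile 0.74); the basal regulator TP63 was 10.8-fold and 5.37-fold higher. Mesenchymal regulators split 6 higher to 9 lower of 21: vimentin (VIM) was 11.1-fold and 73.4-fold higher and fibronectin (FN1) 56.6-fold (51.6 to 62.3) and 178-fold (162 to 196) lower, and the median of mesenchymal and EMT regulators in the MYC library was 0.03 with a mean of −0.53 and a value of −0.14 without the expression filter. Matrix genes had 11 of 25 lower and 5 higher (median −0.49, percentile 0.64), with COL16A1 48.2-fold and 72.1-fold higher. TGF-beta and YAP targets had 12 of 19 lower and 1 higher, below every one of the matched random lists; TGFB2 was 39.6-fold and 93.8-fold lower and thrombospondin THBS1 14.6-fold and 21.97-fold lower.

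EGFR and MAPK feedback genes had 6 of 24 higher and 7 lower (median −0.30, percentile 4.09), DUSP4 being 4.01-fold and 6.05-fold lower. Steroid and insulin response genes had 5 of 17 lower and 1 higher (median −0.49, percentile 1.45), the insulin receptor substrate IRS2 by 3.13-fold and 3.52-fold. Vesicle release genes had 3 of 17 higher and 5 lower (median −0.45, percentile 2.79), the tetraspanin CD82 being 3.84-fold and 3.36-fold higher. The median of microRNA processing in the MYC library was −0.10 with 0 of 12 members past 1.5-fold, had a mean of 0.02, and becomes 0.0094 with library totals alone. Of 5 fibroblast markers 3 were lower and 0 higher, FAP by 33.2-fold and 49.3-fold (median −0.92, percentile 1.96), of 3 immune markers 2 were lower, CSF1R by 6.72-fold and 7.61-fold, and of 2 endothelial markers KDR was 2.72-fold and 2.69-fold higher and PECAM1 5.18-fold and 6.45-fold lower. None of the 8 erythroid markers passed the expression filter, and the 13 mitochondrial mRNAs are not analysed here, so those lists gave no value for any library. Replication-dependent histones had 0 of 9 higher or lower (median −0.30, percentile 14.7), and housekeeping genes a median of 0.08 and a mean of −0.06, with 2 of 24 higher and 5 lower, ACTB by 4.65-fold and 4.32-fold.

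In all, 1127 genes were at least 2-fold higher and 1299 at least 2-fold lower than both controls in the library labelled MYC, 19.4% of 12484, against a mean of 74.9 and a maximum of 97 in 100 simulated sets of unchanged libraries. The majority turns to 1286 higher and 1169 lower with library totals alone, and to 1624 and 1573 with vector alone as control. With the controls taken as replicates of 1 group, edgeR called 2788 genes and DESeq2 1756. No difference here has a replicate check, and the intervals cover counting error alone. Library totals alone move the median of all genes from 0.04 to 0.14 in this library and from 0.01 to −0.09 in the one labelled miR-105.

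In the library labelled miR-105, genes of DNA replication and mitosis were far above both controls and above the library labelled MYC. All 34 measured G2/M genes were at least 1.5-fold higher, with a median log2 fold of 5.10, or 34.3-fold, and all 39 G1/S genes, with a median of 3.74, or 13.3-fold. The median level of the G2/M genes was 207 CPM here. It was 7.14 CPM in the vector library, 4.51 in GFP and 10.1 in the one labelled MYC. Whether these genes were raised in this library or low in the others cannot be told from 1 library each. Genes of ribosome biogenesis, nucleotide and cholesterol synthesis were higher with them, while steroid and insulin response genes, inflammatory NF-kB targets and p53 targets were lower. Replication-dependent histones, a list fixed as a check of RNA quality, had 8 of 9 members lower and a median of −2.01. That median was −1.83 with undetected members at their bound and −0.48 without the expression filter. The 27 list genes held 156 reads in this library, with a median of 1.57 CPM over the 9 measured. In poly(A) libraries such few reads are not taken here as a measure of the cell cycle. The library labelled miR-105 also had the highest MYC mRNA.

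RRM2, a subunit of ribonucleotide reductase, stood at 624 CPM against 3.03 and 5.35, 206-fold (142.5 to 311) and 117-fold (92.8 to 149) higher. MCM10, a replication initiation factor, was 165-fold (75.6 to 452) and 186-fold (93.7 to 432) higher, and MKI67, the proliferation antigen, 103-fold (84.9 to 126) and 78.5-fold (68.4 to 90.6). The spindle checkpoint kinase BUB1 was 96.1-fold (62.0 to 158) and 92.8-fold (65.1 to 137) higher, and the transcription factor MYBL2 was 96.6-fold (66.6 to 146) above vector. DTL, KIF14 and EXO1 were 172-fold (73.3 to 532), 89.1-fold (46.6 to 196) and 107-fold (45.3 to 331) above vector. DLGAP5, CEP55, KIF20A and ANLN, all of mitosis or cytokinesis, were between 59.3-fold and 86.5-fold above vector. PLK1 was 44.8-fold and 69.3-fold higher, CCNA2 20.1-fold and 22.1-fold, and the tubulin TUBA1B, a housekeeping list member, 16.3-fold above both controls.

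At the low end, MYBPC1, a myosin-binding protein, had 0 reads against 182 and 144 CPM, at least 387-fold and at least 306-fold lower. The iron-binding lipocalin LCN2 was 145-fold (99.6 to 220) and 148-fold (102 to 225) lower, and the pro-apoptotic BMF 142-fold and 167-fold. PSG4, at 1 read, was 371-fold (66.3 to 14674) and 274-fold (49.1 to 10860) lower, and the GABA receptor subunit GABRP, at 2 reads, 150.3-fold (41.3 to 1245) and 274-fold (75.7 to 2265). The glycosyltransferase GALNT15 was 143-fold and 112-fold lower, the proton pump subunit ATP6V1B1 111-fold and 85.3-fold, and the cytochrome P450 CYP4B1 95.3-fold and 63.9-fold. FBXO32, a ubiquitin ligase subunit induced by FOXO factors, was 61.4-fold and 86.8-fold lower, and YPEL3, the guanylate-binding protein GBP2 and the alkaline phosphatase ALPP were 79.0-fold, 71.9-fold and 53.4-fold below vector.

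MYC targets, ribosome biogenesis genes and translation factors were higher, unlike ribosomal protein genes and the MAX partners. Of 55 MYC targets 51 were higher and 0 lower (median 1.60, percentile 100), and of 51 ribosome biogenesis genes 48 were higher and 1 lower (median 1.33, percentile 100), RRS1 by 4.69-fold and 5.43-fold and TAF1D lower by 2.19-fold and 1.61-fold. Translation factors and tRNA synthetases had 24 of 32 higher and 2 lower (median 1.08, percentile 100), EIF5A by 3.90-fold and 5.12-fold, whereas EEF2 was 2.13-fold and 1.74-fold lower. Ribosomal protein genes had a median of −0.44 (percentile 0.27) with 3 of 72 higher, but the median of cytosolic ribosomal proteins in the miR-105 library was −0.88 against vector alone and 0.025 against GFP alone. The MAX partners had 2 of 10 higher and 3 lower: MXD4 was 6.96-fold and 6.97-fold lower and MNT 2.29-fold and 2.44-fold lower, with MXD3 2.54-fold and 3.35-fold and MGA 4.07-fold and 2.25-fold higher. The median of MYC network (MAX partners) in the miR-105 library was −0.28 (percentile 15.4), and becomes 0.12 with undetected members at their bound and 0.06 among members of at least 5 CPM.

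Biosynthetic lists had more members higher than lower. Serine, one-carbon and nucleotide genes had 25 of 28 higher and 0 lower (median 1.94, percentile 100), thymidylate synthase TYMS by 14.3-fold and 14.1-fold and PSAT1 by 10.9-fold and 8.36-fold. Cholesterol genes had 17 of 22 higher and 1 lower (median 1.57, percentile 100), INSIG1 by 12.5-fold and 11.8-fold and HMGCS1 by 8.65-fold and 6.85-fold, with TM7SF2 4.88-fold and 3.65-fold lower. Fatty acid genes had 8 of 15 higher and 3 lower (median 1.402, percentile 99.99), FABP5 by 31.3-fold (22.7 to 44.3) and 48.1-fold (34.7 to 68.4). Glycolysis genes had 13 of 23 higher and 0 lower (median 0.88, percentile 99.8), among them ENO1 at 3.25-fold and 4.01-fold. Glutamine and amino acid genes had 11 of 20 higher and 2 lower (median 0.92, percentile 99.9), ODC1 by 9.36-fold and 10.2-fold, while glutamine synthetase (GLUL) was 13.6-fold and 15.9-fold lower here and 2.77-fold and 2.38-fold higher in the library labelled MYC. Oxidative phosphorylation genes had 10 of 36 higher and 0 lower (percentile 95.7), and the median of oxidative phosphorylation, nuclear encoded in the miR-105 library was 0.42, but 0.21 against vector alone and 0.60 against GFP alone. Heat shock chaperones had 15 of 19 higher and 0 lower (median 1.23, percentile 100), HSP90AA1 by 3.74-fold and 3.63-fold. The unfolded protein and ATF4 list had 9 of 25 higher and 6 lower, with a median of 0.26 and a mean of −0.02. Housekeeping genes, the list fixed as a check of scaling, had 12 of 24 higher and 1 lower (median 0.61, or 1.53-fold, percentile 98.5). Their median with the MYC label was 0.08. Whether the departure with the miR-105 label comes from scaling or from the genes themselves was not tested.

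Hormone-responsive genes, p53 targets and NF-kB targets were lower. Steroid and insulin response genes had 14 of 17 lower and 0 higher (median −1.64), below every one of the matched random lists: TXNIP, an arrestin that limits glucose uptake, was 19.1-fold (17.7 to 20.5) and 25.3-fold (23.5 to 27.2) lower, and PIK3IP1, at 3 reads, 48.9-fold (16.5 to 239) and 64.5-fold (21.9 to 314). CDK inhibitors and p53 targets had 13 of 23 lower and 2 higher (median −0.76, percentile 0.08), TP53INP1 by 10.6-fold and 17.4-fold and CDKN1A by 2.46-fold and 2.53-fold. Inflammatory and NF-kB targets had 11 of 21 lower and 5 higher (median −1.20, percentile 0.04), NFKB2 by 6.30-fold and 5.09-fold. Interferon-stimulated genes had 16 of 33 lower and 4 higher (median −0.75, percentile 0.27), STAT2 by 6.10-fold and 7.10-fold. MHC class I genes had 5 of 16 lower and 1 higher (median −0.35, percentile 8.68), HLA-E by 3.02-fold and 2.37-fold. Hypoxia genes had 7 of 19 lower and 1 higher (median −0.33, percentile 9.64), CITED2 by 16.7-fold and 13.9-fold, and lysosome genes 8 of 20 lower and 2 higher (median −0.42, percentile 2.92), GABARAPL1 by 16.9-fold and 18.1-fold. EGFR and MAPK feedback genes were higher, with 16 of 24 members and 1 lower (median 1.02, percentile 99.99): FOSL1 by 20.7-fold and 23.9-fold, and the ligand AREG by 14.7-fold and 24.6-fold. Immediate stress genes had 2 of 14 higher and 5 lower (median −0.21, percentile 28.0), ATF3 by 6.44-fold and 8.91-fold.

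Epithelial genes were mixed in the library labelled miR-105. Junction genes had 11 of 28 lower and 1 higher (median −0.61, percentile 0.69), claudin CLDN1 by 12.7-fold and 17.5-fold. TGF-beta and YAP targets had 8 of 19 lower and 1 higher (median −0.54, percentile 1.36), whereas TGFBI was 3.61-fold and 3.19-fold higher. Squamous genes had 10 of 23 lower and 7 higher (median −0.63, percentile 10.8, −0.15 without the expression filter), TGM1 by 9.48-fold and 7.12-fold. Basal genes had 7 of 17 lower and 3 higher (median −0.07, percentile 46.7): keratin KRT17 was 9.04-fold and 6.70-fold lower and integrin ITGA6 8.76-fold above vector. Luminal genes split 4 to 4 of 11, MUC1 being 6.95-fold and 6.39-fold lower; the median of luminal in the miR-105 library was 0.12 with a mean of −0.15, and becomes −0.54 among members of at least 5 CPM. Mesenchymal regulators split 4 to 4 of 21 (median −0.07, percentile 45.2, −0.02 with undetected members at their bound), CDH2 being 6.73-fold and 6.15-fold higher. The median of extracellular matrix and collagens in the miR-105 library was 0.05 with 8 of 25 higher and 7 lower, 0.33 with undetected members at their bound, and −0.05 with library totals alone; COL6A3 was 26.0-fold and 48.6-fold higher. MicroRNA processing genes had 2 of 12 higher and 1 lower (median 0.43, percentile 84.2), AGO4 by 3.55-fold and 5.44-fold, and vesicle release genes 1 of 17 higher and 3 lower (median −0.06, percentile 37.7). Of 5 fibroblast markers 2 were higher and 1 lower (median −0.20, mean 1.02), decorin (DCN) by 7.30-fold and 4.34-fold, and both measured endothelial markers and 2 of 3 immune markers were lower, KDR by 18.9-fold and 19.1-fold.

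At the 2-fold threshold, 1833 genes were higher and 2071 lower than both controls in the library labelled miR-105, 31.3% of 12484, against a mean of 98.7 and a maximum of 125 in the simulated unchanged sets. The majority turns to 1687 higher and 1552 lower at a mean of at least 5 CPM, and to 1672 and 1637 with a pseudocount of 2. The pooled-control tests called 4878 genes with edgeR, 2468 higher and 2410 lower, and 3357 with DESeq2, 1606 higher and 1751 lower. This was the shallowest library, and as with the other label the differences have no replicate check.

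**Figure D2:**
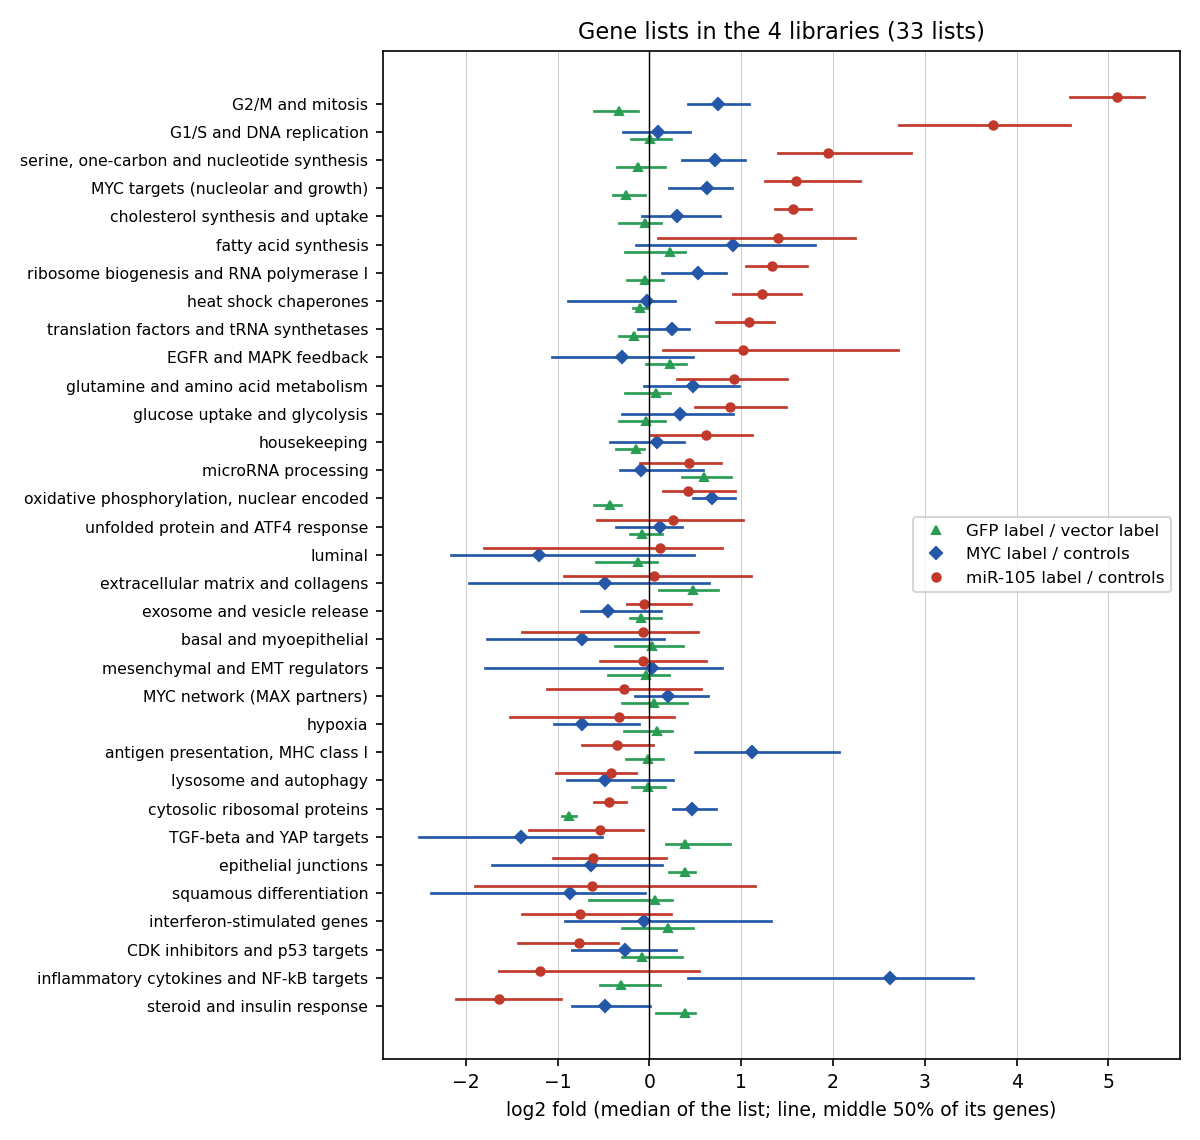
Median log2 fold change of 33 gene lists (x axis; points) with the middle 50% of members (lines), for GFP over vector (green triangles), the library labelled MYC (blue diamonds) and the library labelled miR-105 (red circles), the latter pair as the mean against both controls. The G2/M median is 5.10 with the miR-105 label and 0.75 with the MYC label, the NF-kB list −1.20 and 2.62, and the medians of heat shock, interferon and microRNA processing genes with the MYC label and of matrix genes with the miR-105 label change sign when library totals alone set the scale.

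The control libraries, vector and GFP, show how far a single pair of libraries without either construct differed. The GFP library had lower mRNA of ribosomal protein genes, 71 of 72 at least 1.5-fold below vector with a median log2 fold of −0.88, and 12 of 36 oxidative phosphorylation genes were lower and 0 higher, with a median of −0.43. G2/M genes had 9 of 34 lower and 0 higher (median −0.34), and MYC targets 4 of 55 lower and 1 higher (median −0.25). Matrix genes had 11 of 25 higher and 2 lower (median 0.48), microRNA processing genes 6 of 12 higher and 0 lower (median 0.59), TGF-beta and YAP targets 8 of 19 higher and 0 lower (median 0.39), and epithelial junction genes 5 of 28 higher and 0 lower (median 0.39). Among matched random lists, the ribosomal protein, oxidative phosphorylation and MYC target medians stood at percentile 0, and G2/M at 0.01. Matrix genes stood at percentile 99.98 and junction genes at 99.92. Percentiles near 0 or 100 were thus reached between libraries without either construct, and do not by themselves mark an effect of MYC or miR-105. Across 12131 genes, which are not independent replicates, GFP over vector followed transcript length, with a Spearman correlation of 0.601 and a median of −0.30 in the shortest quartile and 0.44 in the longest, and the group values given here are not corrected for it. After removal of that trend, 27 of the 72 ribosomal protein genes stayed at least 1.5-fold lower, with a median of −0.507. The matrix glycoprotein tenascin C (TNC) was 8.57-fold (5.66 to 13.6) higher, and POMK, NBEAL1, SORL1 and KIAA0754 between 4.86-fold and 6.44-fold higher. VIM was 6.64-fold (5.51 to 8.04) lower, IGF2 6.73-fold, CADM3 5.84-fold, EMP3 4.59-fold, and ZNF729, with 0 reads, at least 43.4-fold. FN1 was 3.14-fold higher. At 2-fold, 382 genes were higher and 128 lower in GFP, 4.09% of 12484, a total of 510 where simulated unchanged libraries, drawn at the dispersion of this same pair, gave a mean of 426.5 and a maximum of 470. That split was 306 to 168 with DESeq2 size factors and 310 to 191 with the deposited values unscaled, so the share of higher genes, 74.9%, becomes 64.6% and 61.9%. It was 412 to 389 without the expression filter and 238 to 40 with a pseudocount of 2. Correlation of log2 CPM across genes, which are not independent replicates, was 0.975 between the controls and between 0.773 and 0.832 for pairs with the library labelled MYC.

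Genes counted in both labelled libraries were compared by direction. Higher in both were 358 genes, where 165 would be shared by independent lists of these sizes. Lower in both were 576, against 215 for independent lists. The simulated unchanged sets gave at most 7 and 6, but they hold no changed genes and few calls, means of 98.7 and 74.9. They do not show what 2 changed libraries with the same controls would share. Genes higher with the miR-105 label and lower with the MYC label numbered 75 (191 for independent lists), and the reverse 148 (187). The metal-binding MT2A and MT1G, which resemble other metallothioneins, were 22.2-fold and 15.6-fold above vector in the library labelled miR-105 and 19.2-fold and 21.5-fold in the one labelled MYC. The lysosomal protease CTSC was 22.4-fold and 30.2-fold above vector, the antiviral enzyme OAS3 19.2-fold and 26.0-fold, and the lipid transporter MFSD2A 24.99-fold and 104-fold. Lower in both were LCN2, CD22, PSG4 and the paralogs ALPP and ALPPL2, ALPP by 53.4-fold and 55.5-fold below vector. Opposite directions were seen for cathepsin V (CTSV), 7.83-fold above vector with the miR-105 label and 48.1-fold below it with the MYC label, and for ADAM12, POSTN, PADI4 and PDE1C. In the reverse direction stood AQP3, a glycerol and water channel, 7.24-fold below vector with the miR-105 label and 5.98-fold above it with the MYC label, and ALDH3A1, BBOX1, ACSS1 and PDZK1IP1. Across genes, the miR-105 over vector and MYC over GFP log2 folds, which share no control, had a Pearson correlation of 0.237 and a Spearman correlation of 0.240, with a covariance of 0.433 against 0.000284 in simulated unchanged libraries. With both taken against vector the correlation was 0.316 and the covariance 0.557, where simulation gave 0.495 and 0.115 from the shared control alone. Genes are not independent replicates, and each control is a single library, so part of the overlap may come from the controls they share.

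**Figure D3:**
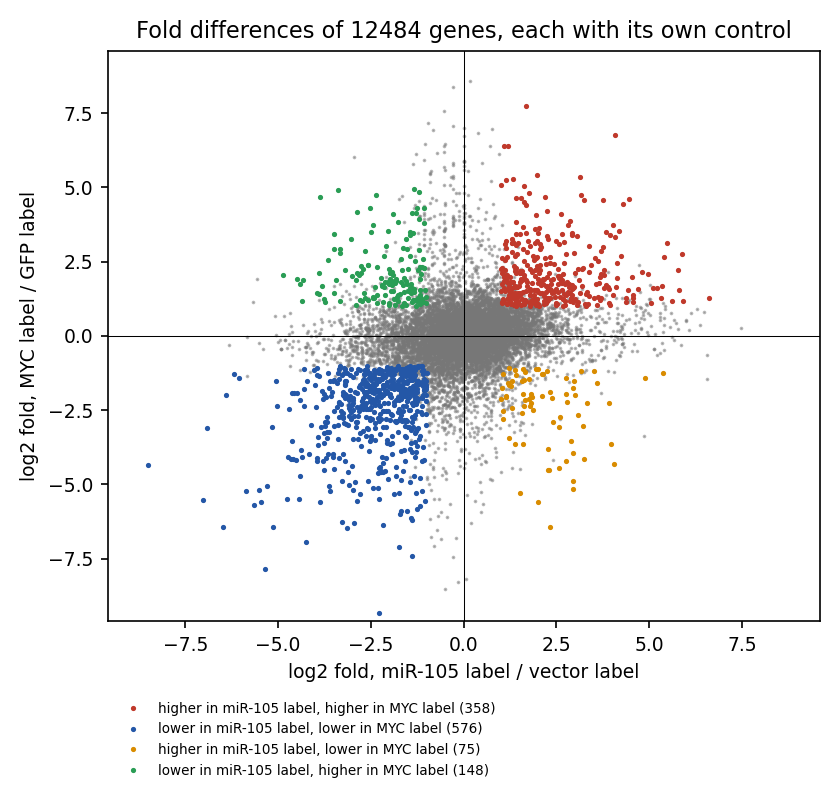
Log2 fold of 12484 genes in the library labelled miR-105 over vector (x axis) and in the library labelled MYC over GFP (y axis), with genes counted in both against both controls coloured: higher in both red, lower in both blue, higher with the miR-105 label and lower with the MYC label orange, the reverse green. The 358 red and 576 blue genes outnumber the 75 orange and 148 green ones.

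MXI1 and TJP1 carry matches to the miR-105-5p seed in their 3′ UTRs. MXI1 has an 8-base match, GCATTTGA, at 10:110286013-110286020 of GRCh38, position 1026 of a 3′ UTR of 1519 bases. TJP1 has the same 8 bases at 15:29701259-29701266 and 15:29700675-29700682, and the 7-base GCATTTG at 15:29701471-29701477 and 15:29700816-29700822, within a 3′ UTR of 2228 bases. Genes with such sites were not lower as a class. In the library labelled miR-105, the 3013 genes with a site of 11819 had a median log2 fold 0.11 (0.06 to 0.16) above the genes without one, at percentile 73.7 of 3229 control words, whose middle 95% ran from −0.13 to 0.17. With vector alone as control the miR-105 seed site shift was 0.26, and with GFP alone 0.0032. The miR-105 seed site shift in the MYC library was 0.04 (0.01 to 0.08; percentile 80.3) but −0.068 with GFP alone as control, and GFP over vector 0.27 (0.24 to 0.29; percentile 56.0). With 8-base sites alone, 528 genes, the shift was 0.10 with the miR-105 label and 0.07 with the MYC label. The 257 genes with a site for the other arm, miR-105-3p, gave −0.01 (percentile 54.3) and −0.04 (percentile 44.5).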

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

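The deposited pseudo-counts without scaling were chosen as an alternative only after the results had been seen, and no test reported here decides between the settings. No paired analysis was possible because each group holds 1 library and the labels give no replicate numbers. Of 790 values of list medians under the alternatives, 774 stayed within their interval of the reported one, 15 moved and 1 reversed, and of 4782 values for named genes 4578 stayed and 204 moved. Sign changes of list medians close to 0, named below, are counted as stayed or moved. The 1 reversal is therefore not the number of medians that changed sign. Without the settings that use a single control, 639 of 646 list values and 3411 of 3586 gene values stayed. The counts follow the threshold by construction. At 1.5-fold and 4-fold, the genes at least 2-fold different in the miR-105 library against both controls (3904) become 6085 and 1351, the genes at least 2-fold different in the MYC library against both controls (2426) become 4217 and 890, the genes at least 2-fold different between the GFP and vector libraries (510) become 2490 and 21, and the genes called in the same direction in the miR-105 and MYC libraries (934) become 1947 and 213. Without the expression filter the GFP and vector libraries differed in 801 genes, and with a pseudocount of 2 in 278, because low genes enter or are shrunk. With GFP alone as control 1433 genes shared a direction, since fewer conditions had to be met. The correlation across genes of the miR-105 and MYC fold changes, crossed controls, 0.237, was 0.209 with a pseudocount of 0.1, 0.284 with the controls swapped, 0.316 with both against the vector library and 0.302 with both against the mean of the controls. The choice of control moved values that follow the difference between vector and GFP. With vector alone and then GFP alone, the median of cytosolic ribosomal proteins in the miR-105 library, −0.44, was −0.88 and 0.025, the latter a reversal. Likewise the median of cytosolic ribosomal proteins in the MYC library, 0.46, was 0.0047 and 0.91, the median of oxidative phosphorylation, nuclear encoded in the miR-105 library, 0.42, was 0.21 and 0.60, and the median of oxidative phosphorylation, nuclear encoded in the MYC library, 0.68, was 0.49 and 0.90. The median of G2/M and mitosis in the MYC library, 0.75, was 0.95 with GFP alone. The miR-105 seed site shift, 0.11, was 0.26 with vector alone, 0.0032 with GFP alone and 0.061 without the expression filter, and the miR-105 seed site shift in the MYC library, 0.04, reversed to −0.068 with GFP alone. Library totals alone gave −0.54 and 0.57 for the ribosomal protein medians of the libraries labelled miR-105 and MYC and 0.22 for the median of unfolded protein and ATF4 response in the MYC library, which the shift of all genes under that scaling accounts for in direction. A pseudocount of 2 gave 4.65 for the median of G2/M and mitosis in the miR-105 library. Filters on low genes changed which members counted: the median of squamous differentiation in the MYC library was −0.40 without a filter and −2.38 at a mean CPM of at least 5, and the median of RNA quality: replication-dependent histones in the miR-105 library was −0.48 without a filter. Where no reason is given the cause was not tested. Medians close to 0 changed sign under single settings, as for mesenchymal, luminal, matrix, interferon, heat shock, microRNA processing, fibroblast, immediate stress and housekeeping genes. Depth limits the low end: 3 reads are worth 0.217 CPM in the GFP library and 0.471 CPM in the one labelled miR-105, and genes with 1 to 3 reads numbered 1447 there and 2870 in the vector library.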

Other observations

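The tests of a sparser culture, of depth, of a share of other cells and of another cell line were chosen only after the results they bear on had been seen, as were the genes CDKN2A, CDKN2B, MTAP, SFTPD, CTGF, CYR61, AJUBA, LATS2 and CRIM1 named here. Some genes differed from both controls in opposite directions in the labelled libraries. Thrombospondin THBS1 stood at 64.8 CPM with the MYC label and 2337 CPM with the miR-105 label, against 948 and 1422 CPM in the controls, and the kinase receptor KDR at 88.9 and 1.73 CPM, against 32.7 and 33.0. The tight junction protein TJP3 was 2.69-fold and 2.26-fold higher with the MYC label and at 5 reads, 32.9-fold and 39.1-fold lower, with the miR-105 label. The mesenchymal genes MYL9 and TAGLN, which encode contractile proteins, were lower with both labels, TAGLN at 6.35 CPM (MYC) and 23.1 CPM (miR-105) against 102 and 159 CPM in the controls.

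In the library labelled miR-105, all 34 G2/M genes were higher, with a median of 34.3-fold, and MYC mRNA was highest there. Thinning all libraries to the shallowest, which is the one labelled miR-105, left the G2/M median at 5.153 in log2. The greater depth of the other libraries thus did not produce that median. Random thinning keeps the expected CPM of a gene, so a large fall was hardly possible and nothing more is drawn from it. A sparser culture at harvest would raise YAP targets, but the 7 measured ones (CTGF, CYR61, AMOTL2, AXL, AJUBA, LATS2 and CRIM1) had a median log2 fold of −0.851 (bootstrap 95% interval −1.719 to −0.070). Single values ran from −1.81 (CRIM1) to 0.30 (AXL). They show no rise of these 7 genes as a set. Of the wider list of TGF-beta and YAP targets, 8 of 19 were lower and 1 higher. THBS1, which is not among the 7, stood above both controls here. The set of 7 therefore does not decide on culture density. Culture density itself was not measured here, and other differences of culture state were not tested. A swap of the miR-105 and MYC labels cannot be told apart from correct labels: against the mean of both controls, genes with a miR-105-5p site were lower in neither library, at percentile 73.74 of control words with the miR-105 label and 80.33 with the MYC label, so the test that was to decide it had nothing to read, and of the single genes with sites MXI1 was lower with the miR-105 label (5.82-fold and 6.37-fold, against 1.03-fold and 1.12-fold with the MYC label) but TJP1 was further down with the MYC label (2.66-fold and 3.91-fold, against 1.21-fold and 1.77-fold). Swapped labels, an effect of miR-105 through MXI1 or MYC, and other differences between 2 single cultures may each underlie the pattern, and the design cannot separate them.

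In the library labelled MYC, genes well expressed in both controls were nearly silent and silent genes were on: of 4207 genes at 50 CPM or more in both controls, 12 stood under 1% of both here (among them KLK5, GRHL2 and CLDN4), and 12 were on in the same sense, including FGFR3, LTF and SFTPD, against 4 and 3 with the miR-105 label. For the genes that are off, a share of other cells beside control-like MCF10A cells is argued against by those 12, since the remaining cells would still supply their transcripts. For the genes that are on, a share of other cells stays open: the 5 measured fibroblast markers had a median log2 fold of −0.921, but the other marker lists had too few measured members and other epithelial cells were not tested. CDKN2A lies in a deletion that MCF10A cells carry (GRCh38 9:21967753-21995301). CDKN2A, with its neighbours CDKN2B and MTAP, had 0 reads in this library as in the others. That argues against a cell line that expresses CDKN2A in place of MCF10A. Any line that has lost or does not express CDKN2A stays open, so these reads do not identify the cells as MCF10A. Swapped labels stay undecided here too (percentile 73.74), and growth of a subclone with a changed epithelial state is a possible explanation that was not tested.

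Between the controls, ribosomal protein genes were lower in GFP, with 71 of 72 at least 1.5-fold below vector and a median log2 fold of −0.88 (−0.90 to −0.84). The log2 ratio of the controls followed transcript length across 12131 genes, which are not independent replicates, with a Spearman correlation of 0.601. Its medians were −0.30, −0.09, 0.14 and 0.44 from the shortest to the longest quartile. For the libraries labelled miR-105 and MYC, the mean of the folds against both controls gave correlations of −0.004 and −0.019. Opposite length trends against vector and against GFP can cancel in that mean. The log2 folds against vector and against GFP differ by exactly the log2 ratio of the controls, so they cannot both be free of the trend. The crossed-control correlation uses such folds, and the unchanged libraries simulated for it held no length trend. After the length trend was removed the median was −0.507 (−0.58 to −0.45) and 27 of 72 members stayed at least 1.5-fold lower, so length may account for part. The remaining median is just past −0.5, the bound set beforehand for arguing against length as the cause. Its interval spans that bound, so the question is left open. Removing the trend with GC content left −0.937 (−0.97 to −0.87) and 72 of 72 members, which argues against GC content as the cause. No biological explanation was tested, since nothing in the design links GFP to ribosomal protein mRNA.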
